A study of Mus musculus with 88 samples.

How the data were processed

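Gene expression was measured in 4 transplanted mouse tumours after carbon ions or gamma rays, on 88 arrays of total RNA, each hybridised with RNA of a single sample. Per the labels, RNA was labelled with Cy5 in a single colour by the CodeLink protocol, and the values deposited for each probe are an intensity on a linear scale. The scanner software, the background method and the scaling rule are not given in the sources used here. From the values themselves, each array had been scaled to a median near 1, and values ran down to -0.271, so that background had been subtracted. Of all values 0.751% were missing and 0.150% not above 0.

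Samples were grouped by the tumour, beam, dose and time that their titles give, which made 44 groups of 2 arrays. In most groups the titles number the arrays 1 and 2, and at day 1 of the gamma arm 3 and 4. Of the 36227 probes, 21615 had 1 gene symbol in the platform annotation, 681 several and 13931 none. Probes with several symbols were not named. Symbols were updated through the Entrez number, which matched for 21487 probes, to a RefSeq gene table of assembly GRCm38.p6, used for names only. For each of 18069 genes the probe with the highest mean log2 value was kept, which mattered for the 3002 genes with several probes. Bax and Ccnb1 had no probe of their own.

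Values at or below 0 were set to missing and log2 was taken, with no further normalization, since the array medians lay close together. Genes in the lowest 25% of mean log2 value, and genes with values on fewer than 80% of arrays, were left out, and 13465 genes were tested. The precision is limited by the number of arrays. A fold change of a dim gene is compressed or stretched by the unknown background step, and this is largest near the low end.

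Differences were tested with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8). A single linear model gave each of the 44 groups its mean, which left 44 residual degrees of freedom, with a prior of 7.30 from the empirical Bayes step. A response is the irradiated group minus the untreated group of the same tumour and the same beam's arm, averaged over the 4 tumours, and its error is that between arrays of a group. Responses were taken at 6 h, day 1 and day 3 after 30 Gy of carbon ions and 30 or 50 Gy of gamma rays. The differences tested were those between the beams, between the gamma doses, between day 3 and 6 h of carbon ions, and between the untreated carcinomas and fibrosarcomas. A moderated F test with 3 contrasts asked whether the carbon-ion response differed between tumours. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, two-sided, and a gene passed under 0.05.

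The 21 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives other than those 2 stated as added. The lists share no gene. They are p53 targets, G2/M and mitosis, DNA replication, DNA repair, oxidative stress, unfolded protein and heat shock, hypoxia and glycolysis, immediate-early genes, inflammatory cytokines and NF-kB targets, and interferon-stimulated genes. The others are markers of T and NK cells, B cells, macrophages and monocytes, MHC class II and dendritic cells, neutrophils, endothelium, fibroblasts and matrix, keratinocytes and epithelium, skeletal muscle, fat cells and red blood cells. Each list was tested against all other genes with limma's camera, with a preset correlation between genes of 0.01, on the 10604 genes with a value on every array, and p-values were adjusted over the 21 lists of a comparison. Counts of members that passed rest on all members tested.

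The genes named were those with the largest change. Against untreated tumours these were 10 up and 5 down after carbon ions and 5 up and 3 down after gamma rays, with the same sign in all 4 tumours. For differences between beams, doses and times 5 each way were taken, for tumour differences the 5 with the largest F at each time, and for carcinoma against fibrosarcoma 10 each way. Up to 4 members of a list with the largest change were added, and Cdkn1a, Mdm2, Ccng1 and Plk1 always. Predicted genes and unnamed transcripts were counted but passed over.

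The fit was tested on simulated values. For carbon ions at 6 h over the 4 tumours, 85.1% of genes changed 1.25-fold were recovered, 95.5% at 1.5-fold and 100% at 2-fold, with 5 false among 192 calls. In NR-S1 alone the shares were 19.4%, 61.2% and 100%, with 6 false among 126 calls, and in the F test 4.48%, 46.3% and 95.5%, with 6 false among 103. A 1.25-fold shift was called for 21 of 21 lists, with 0 calls without it. False calls at correlations estimated here, up to 0.168, were not tested.

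The alternatives were quantile normalization, centring each array on its median, an offset of 0.0743 before the log, no filter on dim genes, leaving out the dimmest 50% of genes, the mean of all probes of a gene, only the arrays compared, an intensity trend with a robust prior, a fold change of at least 1.5, the replicate number as a block, the untreated arrays of both arms as control, the tumours as the replicates, and each array left out in turn. For lists they were an estimated correlation and the fry test. After the data were seen 2 more were added: leaving out the 8 arrays whose 1st percentile was above 0.2, and aligning the low ends of all arrays by a shift of each array's lowest percentile. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.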

Results

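RNA was measured on 88 one-colour arrays of 4 transplanted mouse tumours grown in the hind leg. NR-S1 and SCCVII are labelled squamous cell carcinomas, NFSa a spontaneous fibrosarcoma and #8520 a fibrosarcoma that arose after irradiation. Each tumour received 30 Gy of carbon ions, or 30 or 50 Gy of gamma rays, and was taken at 6 h, day 1 or day 3. Each beam had its own untreated tumours. The arrays fell into 44 groups of 2, with 22 arrays per tumour, 32 in the carbon-ion arm and 56 in the gamma arm, 16 of the 88 untreated. The deposited intensities had medians of 1.02 to 1.07 per array, and 159 to 628 of the 36227 probes had no value on an array. Arrays of a group correlated at 0.990 to 0.998 over genes, and the standard deviation of their log2 difference was 0.133 to 0.326, the highest in NR-S1 at day 1 after carbon ions. The labels do not say whether the 2 arrays of a group came from separate animals, so the p-values measure the spread between these arrays only. The 13465 genes tested were compared as means over the 4 tumours, 8 arrays against 8, unless a tumour is named.

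On 8 arrays the dimmest probes were brighter than elsewhere. Their 1st percentile of intensity was 0.297 to 0.378, against 0.0128 to 0.134 on the other 80 arrays. The 8 were the 50 Gy gamma arrays of SCCVII and #8520 at day 1 and day 3.

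**Figure D1:**
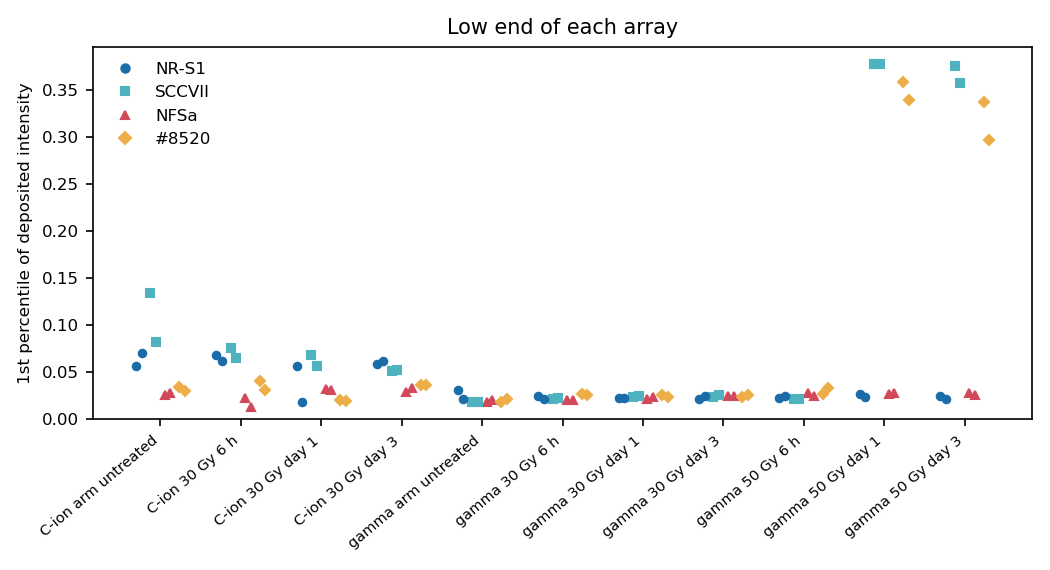
The 1st percentile of deposited intensity (vertical axis) of each of the 88 arrays, by group (horizontal axis). The 8 arrays above 0.2 are the 50 Gy gamma arrays of SCCVII and #8520 at day 1 and day 3.

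Before irradiation NR-S1 carried the keratin programme of a squamous carcinoma, and SCCVII did not. The untreated log2 level of Krt5, the keratin of basal keratinocytes, was 8.38 in NR-S1 and -1.62 in SCCVII, near its -1.70 in NFSa and -1.96 in #8520. Esrp1, a splicing regulator of epithelial cells, stood at 6.53 in NR-S1 and -3.36 in SCCVII, and Krt17, Fxyd3, Krt90, Urah, Aoc1 and Cwh43 likewise had their high level in NR-S1 alone. Dynap and Rps6ka6 were high in both carcinomas, at 5.87 and 4.81 for Dynap and 2.66 and 2.34 for Rps6ka6, against at most -0.80 in the fibrosarcomas. Among the largest decreases, seen in both carcinomas, were the matrix protease Mmp3 at -4.72 (log2, SE 0.0523, adjusted p = 1.6e-54), the Wnt inhibitor Dkk2 at -5.69 (SE 0.0726, adjusted p = 1.2e-51) and the complement protease Masp1 at -5.29, with all 8 carcinoma arrays below all 8 fibrosarcoma arrays for each. The same held for Emx2, Lrch2, Pax6, Nsg1, Slc14a1 and Epb41l3, between -4.95 and -4.11, and for Dmrta1, at -3.29 and -2.90 in the carcinomas. Outside the comparison of alternatives no mean difference is given for genes, like Dmrta1, that lay below 0.134, the highest 1st percentile of the other 80 arrays, in at least 25% of the groups compared, a rule chosen after the data were seen.

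All 31 measured keratinocyte and epithelial markers were higher in the carcinomas (median 2.65, adjusted p = 1.7e-14), but the median was 4.60 above the fibrosarcomas in NR-S1 and 0.12 in SCCVII. Interferon-stimulated genes were lower, 30 of 32 (median -1.44, adjusted p = 1.7e-14), with Rsad2 at -2.37 and Mx2 at -1.97. Their median was -1.74 in NR-S1 and -0.43 in SCCVII. Macrophage markers were lower, 26 of 27 (median -0.90, adjusted p = 9.6e-09), with Ccr2 at -2.14 and Msr1 at -1.84, and this came from NR-S1, at -2.07 against 0.00 in SCCVII. Matrix and fibroblast genes were lower, 25 of 32 (adjusted p = 3.8e-10), with Loxl2 at -3.35 and Acta2 at -2.99. Of 25 hypoxia and glycolysis genes 18 were higher and 4 lower (adjusted p = 1.3e-05), with Car12 at 4.24 and a median of 1.25 in NR-S1 and -0.03 in SCCVII. Of 37 p53 targets 26 were higher and 4 lower (median 0.37, adjusted p = 0.00016), with Perp, a desmosome gene, at 4.52. Skeletal muscle markers were lower in 24 of 27 (adjusted p = 9.5e-08), with a median of -2.15 in SCCVII and 0.19 in NR-S1. In all, 9881 of 13394 genes differed, 5439 higher and 4442 lower in the carcinomas. With each tumour as 1 replicate, limma called 0 genes, and 781 had an unadjusted p under 0.05, so these are differences between these 4 tumours. The list counts adjusted over the list alone were the same for every list given here.

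The first question is what carbon ions change in all 4 tumours. At 6 h the response had 3 parts: p53 targets rose, genes of mitosis and DNA synthesis fell, and genes that call in or mark neutrophils rose. Cdkn1a, the inhibitor of cyclin-dependent kinases that p53 induces, rose 2.41-fold (log2 1.27, SE 0.0961, adjusted p = 2.5e-16). Mdm2, which degrades p53, rose 2.83-fold (SE of the log2 value 0.102, adjusted p = 2.9e-18), and Ccng1, cyclin G1, by 1.52 (SE 0.0650, adjusted p = 1.6e-26). Each rose in 4 of 4 tumours. Plk1, the kinase that drives entry into mitosis, fell by 1.31 (SE 0.0567, adjusted p = 3.0e-26), again in 4 of 4. The largest rise was that of Cxcl2, a chemokine for neutrophils (log2 3.59, SE 0.0801, adjusted p = 2.1e-39), from 1.78 in NR-S1 to 4.49 in NFSa. The related Cxcl3 and Cxcl1 rose by 2.72 and 2.43. S100a9 and S100a8, which form calprotectin in neutrophils, rose by 3.26 and 3.02, with Retnlg at 3.12, the neutrophil collagenase Mmp8 at 2.45, and the acute-phase genes Ptx3 and Saa3 at 2.71 and 2.52. Celf5 rose by 3.52 with little difference between tumours, 2.97 to 3.91. The largest fall was that of Ung, the uracil glycosylase of base excision repair, by 1.87 (SE 0.0536, adjusted p = 1.5e-34). The helicase Pif1 fell by 1.62, the spindle genes Aspm and Kif20a by 1.59 and 1.43, and Sapcd2 by 1.43. All 15 moved the same way in 4 of 4 tumours.

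Of 37 p53 targets 33 rose and 2 fell (median 0.88, adjusted p = 1.4e-34), with Dcxr at 2.12, Ptprv at 1.97 and the death gene Pmaip1 at 1.54. Of 33 genes of G2/M and mitosis 32 fell (median -0.91, adjusted p = 1.1e-35), with Cdc25c at -1.40 and Kif23 at -1.27, and all 32 replication genes fell (median -0.48, adjusted p = 2.4e-18), with Mcm2 at -0.95. DNA repair genes fell more often than they rose, 15 against 3 of 31 (adjusted p = 9.7e-05), with Chek1 at -1.01. Neutrophil markers rose, 13 of 16 (median 0.88, adjusted p = 2.4e-18), and inflammatory cytokines and NF-kB targets rose, 21 of 26 with 1 fall (median 0.60, adjusted p = 9.4e-15), with Il1b at 2.35. Of 21 immediate-early genes 13 rose (adjusted p = 1.5e-06), with Dusp1 at 0.80. Macrophage markers (12 rose and 3 fell of 27, adjusted p = 0.0023), oxidative stress genes (10 rose and 1 fell of 26, adjusted p = 0.0017, with Slc7a11 at 1.45) and adipocyte markers (5 of 11 rose, adjusted p = 0.0333) were called, but not with an estimated correlation (adjusted p = 0.147, 0.104 and 0.108). The adipocyte call was also lost with quantile normalization, the dimmest 50% of genes left out or the untreated arrays of both arms (adjusted p = 0.0872, 0.262 and 0.0760). Adjusted over the list alone, 2 neutrophil markers and 1 immediate-early gene also fell and 11 oxidative stress genes rose, and the other counts were the same. In all, 5433 of 13415 genes passed, 2823 higher and 2610 lower, and 535 of them changed at least 1.5-fold.

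At day 1 the p53 and neutrophil parts persisted, and mitosis genes were not called as a group. S100a9, S100a8 and Saa3 were the largest rises, by 3.15, 3.11 and 3.14 (SE 0.0573, 0.0516 and 0.0734, adjusted p = 1.9e-43, 3.6e-45 and 2.2e-38). They were followed by Cxcl2 at 2.76, Celf5 at 2.60, Retnlg at 2.54, Ces2e at 2.40, Abhd11os at 2.17 and the p53 targets Ptprv at 2.05 and Dcxr at 2.04. S100a9 rose by 0.65 in NR-S1, against 3.10 to 4.47 in the other 3 tumours. Cdkn1a stood at 1.13 and Mdm2 at 0.96, and Ccng1 at 1.51. Plk1, at -0.08, did not pass (adjusted p = 0.243). Of 33 mitosis genes 7 rose and 7 fell (adjusted p = 0.946). Ung fell by 1.49. Fdps, Cyp51 and Lss, enzymes of the sterol pathway, fell by 1.25, 1.23 and 1.22, and Ighm, the heavy chain of IgM made by B cells, by 1.18 (adjusted p from 5.9e-27 to 2.9e-25), all in 4 of 4 tumours. Among 37 p53 targets 32 rose (median 0.77, adjusted p = 8.0e-28), 12 of 16 neutrophil markers rose and 1 fell (median 0.84, adjusted p = 1.6e-16), and 29 of 32 replication genes fell (median -0.34, adjusted p = 7.4e-14). The replication median was -0.30 in SCCVII, -0.52 in NFSa and -0.85 in #8520, but 0.11 in NR-S1. MHC class II and dendritic cell markers fell, 15 of 21 (median -0.34, adjusted p = 1.8e-07), with the transactivator Ciita at -0.70. Endothelial markers rose, 17 of 24 with 1 fall (adjusted p = 0.0023, and 0.0503 against both arms' untreated arrays), with Mmrn2 at 1.19. Matrix genes rose, 20 of 32 with 1 fall (adjusted p = 4.2e-05), with Lum at 1.70 and Dcn at 1.02. Their adjusted p = 0.0674 with an estimated correlation. In the same groups 22 of 27 skeletal muscle markers rose and 3 fell (median 0.61, adjusted p = 8.3e-10), and 7 of 11 adipocyte markers rose (adjusted p = 0.0023, and 0.473 with the dimmest 50% of genes left out), with Adipoq at 2.02. Adjusted over the list alone, 16 MHC class II, 21 matrix and 23 muscle markers passed in these directions, with the other counts the same. In all, 5649 of 13417 genes passed, 3418 higher and 2231 lower, and 589 changed at least 1.5-fold.

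At day 3 interferon, lymphocyte and macrophage genes rose, and genes of mitosis and DNA synthesis fell. Mx1, an antiviral GTPase induced by interferon, rose 6.72-fold (log2 2.75, SE 0.0670, adjusted p = 3.3e-38), in 4 of 4 tumours and by up to 3.36. Gzma, the granzyme A of killer cells, rose by 2.98 (SE 0.0703, adjusted p = 7.4e-39) and Klrk1, the NKG2D receptor, by 2.80. Further interferon-inducible genes were among the largest rises, Gbp8 at 3.24, Slfn4 at 2.91, Phf11a at 2.85 and the complement gene Cfb at 2.80. Apod and Fam3b rose by 2.89 and 2.83. Crct1, a gene of the epidermal differentiation complex, had a mean of 2.82, but rose by 8.14 in NR-S1 and stood at 0.08 in #8520. The largest falls were those of the sterol enzyme genes Idi1 by 3.09 (SE 0.0668, adjusted p = 2.2e-40), Sqle by 2.55, Cyp51 by 2.42 and Fdps by 2.27, and of the elongase gene Elovl6 by 2.22, each in 4 of 4 tumours. Sterol genes were not tested as a group. Cdkn1a was still raised, at 1.14 (adjusted p = 2.5e-15), with Mdm2 at 0.74 and Ccng1 at 0.85. Plk1 was down again, at -1.45 (adjusted p = 4.0e-29).

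All 32 interferon-stimulated genes rose (median 1.61, adjusted p = 1.2e-26), with Oasl1 at 2.68 and Rsad2 at 2.44. Of 20 T and NK cell markers 18 rose and 1 fell (adjusted p = 2.4e-13), with Prf1, perforin, at 2.47 and Ccl5 at 2.29. The list median was 2.67 in NR-S1 and 2.47 in NFSa, and 0.74 in #8520 and 0.18 in SCCVII. Macrophage markers rose, 24 of 27 with 1 fall (median 1.04, adjusted p = 1.1e-11), with Apoe at 2.61 and Aif1 at 1.82, and neutrophil markers rose, 14 of 16 with 1 fall (median 0.94, adjusted p = 4.3e-10). B cell markers rose, 8 of 13 with 3 falls (adjusted p = 0.0028), with Jchain at 2.05. All 33 genes of G2/M and mitosis fell (median -1.28, adjusted p = 7.1e-19), all 32 replication genes fell (median -1.19, adjusted p = 3.5e-15), and 27 of 31 DNA repair genes fell (adjusted p = 4.7e-07), with Blm at -1.44. All 25 hypoxia genes fell (median -0.58, -0.03 in SCCVII, adjusted p = 9.2e-07), with Aldoc at -1.21. Of 37 p53 targets 24 rose and 3 fell (median 0.27, adjusted p = 4.8e-08), and 18 of 26 inflammatory genes rose and 3 fell (adjusted p = 2.2e-06), with Ccl3 at 1.78. Muscle markers rose in 17 of 27 and fell in 2 (adjusted p = 0.0022, and 0.0614 with an estimated correlation). Unfolded protein and heat shock genes fell, 21 of 28 with 3 rises (adjusted p = 0.0127, and 0.220 with an estimated correlation), with the chaperonin Hspd1 at -1.07. Adjusted over the list alone, 25 p53 targets and 1 DNA repair gene rose, with others the same. In all, 9154 of 13415 genes passed, 3548 higher and 5606 lower, and 2083 changed at least 1.5-fold.

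**Figure D2:**
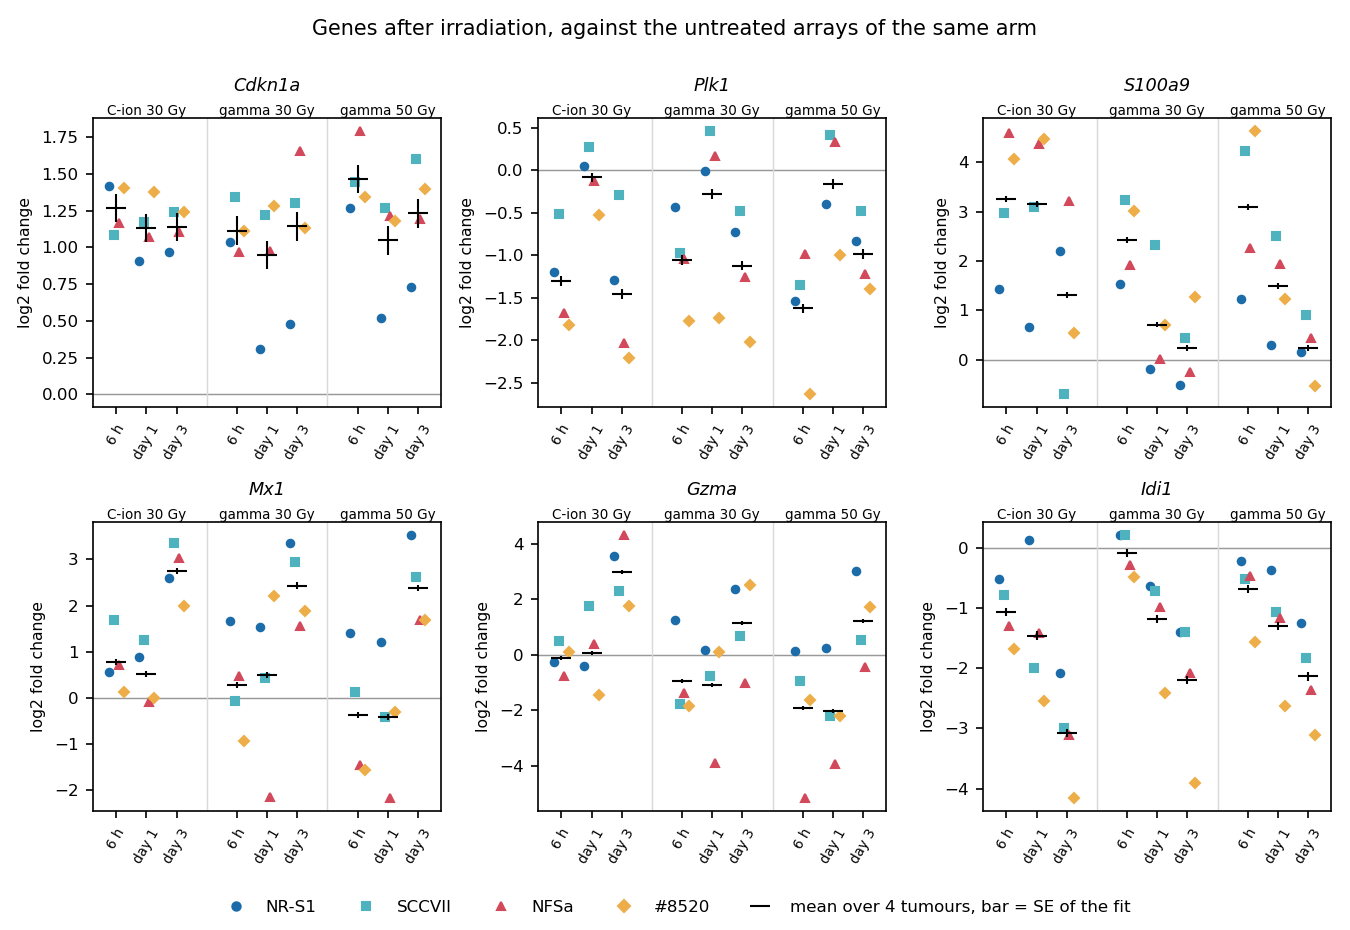
Log2 change against the untreated arrays of the same arm (vertical axis) for Cdkn1a, Plk1, S100a9, Mx1, Gzma and Idi1 by beam, dose and time (horizontal axis), with a point per tumour and the mean with its standard error. Cdkn1a lies above 0 at every point, and Mx1 rises at day 3, by 2.75 after carbon ions and 2.43 after 30 Gy of gamma rays.

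Set against each other, the early and late carbon-ion groups differed most in interferon-stimulated genes, with lymphocyte genes also higher at day 3. From 6 h to day 3, Gbp8 rose by 3.65, Gzma by 3.09 (SE 0.0703, adjusted p = 2.3e-39), the granzyme gene Gzmf by 2.86, Phf11a by 2.84 and the apolipoprotein gene Apoc2 by 2.73. Cxcl2 fell by 2.31 (SE 0.0801, adjusted p = 3.5e-31), Cxcl3 by 2.16, Ccl20 by 1.96 and S100a9 by 1.95, and Idi1 by 2.01. Cxcl2, Cxcl3 and S100a9 fell in 3 of 4 tumours, with values of 0.49, 0.19 and 0.78 in NR-S1. Neutrophil markers as a group did not pass, with 7 up and 8 down of 16 (median -0.04, adjusted p = 0.602). Interferon-stimulated genes rose, 32 of 32 (median 1.63, adjusted p = 3.3e-35), with Ifit2 at 2.46, and T and NK cell markers rose, 18 of 20 (median 1.58, adjusted p = 1.5e-17). Macrophage markers rose, 24 of 27 with 3 falls (adjusted p = 2.0e-10), with Ms4a7 at 1.52, and MHC class II markers 13 of 21 with 3 falls (adjusted p = 0.00014), with Batf3 at 1.26. All 25 hypoxia genes fell (median -0.71, adjusted p = 2.7e-08), with Vegfa at -0.92. Replication genes fell, 30 of 32 (adjusted p = 6.5e-08), and 29 of 37 p53 targets fell with 2 rises (median -0.36, adjusted p = 2.2e-05), with Pidd1 at -1.07, Mdm2 at -0.76 and Ccng1 at -0.67. Plk1 fell by 0.15 and Cdkn1a, at -0.13, did not pass (adjusted p = 0.0209 and 0.249). When adjusted over the list alone, 30 p53 targets fell and 3 rose, and the other counts were the same. In all, 8393 of 13417 genes differed, 2884 higher and 5509 lower at day 3.

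The number of genes that passed in each tumour separately and moved the same way in all 4 was 416 at 6 h, 311 at day 1 and 1706 at day 3, of which 257, 257 and 840 rose. A fit of 1 tumour recovers fewer changes, so these counts can miss shared genes. Of genes called for the mean, 51.3%, 43.3% and 56.5% had one sign in all 4 tumours. A moderated F test of differences between tumours called 6035, 7824 and 8298 genes. At 6 h Gbp4 and Gbp8, guanylate-binding proteins induced by interferon gamma, fell in NR-S1, to -2.67 and -3.67, and rose in SCCVII, to 1.15 and 0.98, and the interferon gamma chemokine Cxcl9 did the same, at -2.86 and 1.00. Retnlg rose by 4.84 in NFSa and 1.20 in SCCVII. Tnni1, a troponin of slow muscle, ran from -2.14 in NFSa to 1.94 in #8520. At day 1 Gbp8, Tnni1, Gbp4 and Retnlg again differed most, with Cyp2f2 at -3.89 in NR-S1 and 2.80 in SCCVII. At day 3 the leading genes were Sprr2f, Crct1, Sprr2g and Psca, which rose in NR-S1 by 7.93, 8.14, 5.75 and 5.19, and Gbp8, at 7.22 in NFSa and 3.28 in NR-S1. Sprr2f stood between -0.00 and 0.06 in the other 3 tumours.

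Gamma rays of 30 Gy, the reference beam at the same dose, gave the same 3 early parts. Celf5 rose by 3.29 (SE 0.0551, adjusted p = 5.9e-45), S100a9 by 2.43 (SE 0.0573, adjusted p = 3.6e-38), Cxcl2 by 2.39, S100a8 by 2.22 and Retnlg by 2.12, each in 4 of 4 tumours. Cdkn1a rose by 1.11, Mdm2 by 1.12 and Ccng1 by 1.47, and Plk1 fell by 1.06 (adjusted p = 3.7e-22). Ung fell by 1.51 (adjusted p = 7.0e-30). Ino80b fell by 1.88 and Mkrn2 by 1.17, with large standard errors of 0.389 and 0.207. Among 37 p53 targets 32 rose and 2 fell (median 0.74, adjusted p = 1.3e-33), with Ddit4l at 2.02. Of 33 mitosis genes 31 fell (median -0.59, adjusted p = 5.7e-27) and 29 of 32 replication genes fell (adjusted p = 6.4e-17), with Mcm7 at -0.89. Neutrophil markers rose, 11 of 16 with 2 falls (median 0.38, adjusted p = 5.0e-11), and 14 of 26 inflammatory genes rose and 2 fell (adjusted p = 4.5e-06), with Cxcl5 at 1.33. T and NK cell markers fell, 15 of 20 (median -0.49, adjusted p = 5.4e-10), with Prf1 at -1.01 and Gzmb at -0.92. The list median was 0.46 in NR-S1 and from -0.92 to -0.63 in the others, and against the untreated arrays of the carbon-ion arm it was 1.21 in NFSa and from -0.90 to -0.10 in the others. Muscle markers rose, 22 of 26 (median 0.68, adjusted p = 1.3e-16), with a median of 2.67 in SCCVII and -1.17 in NR-S1. Interferon-stimulated genes fell, 17 of 32 with 3 rises (adjusted p = 2.5e-05, and 0.0816 with an estimated correlation). Their medians were 0.77 in NR-S1, 0.29 in NFSa, -0.54 in SCCVII and -1.10 in #8520. MHC class II markers fell, 12 of 21 with 1 rise (adjusted p = 0.00056, and 0.144 against the untreated arrays of both arms). Adjusted over the list alone, 32 mitosis and 31 replication genes fell, 23 muscle markers rose and 15 inflammatory genes rose with 3 falls, and for interferon and MHC class II 18 and 13 genes fell. In all, 5060 of 13434 genes passed, 2591 higher and 2469 lower.

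At day 1 after 30 Gy of gamma rays p53 targets led, without the neutrophil genes that led after carbon ions. Celf5 rose by 2.24 (SE 0.0551, adjusted p = 3.5e-37), Ptprv by 2.06 (SE 0.0498, adjusted p = 2.3e-37), Hoatz by 1.94, Ddit4l by 1.76 and Ces2e by 1.70. Gbp8 fell by 2.74 and Cxcl9 by 2.39 (adjusted p = 1.0e-39 for each), and the itaconate enzyme gene Acod1 by 1.71, most of all in NFSa, at -7.15, -5.42 and -5.14. Cdkn1a rose by 0.95, Mdm2 by 0.92 and Ccng1 by 1.40, and Plk1 fell by 0.28 (adjusted p = 6.2e-05), with -1.74 in #8520 and from -0.00 to 0.47 in the other 3. Of 37 p53 targets 27 rose (median 0.54, adjusted p = 2.1e-21) and 26 of 32 replication genes fell (adjusted p = 2.1e-10), with Ccne2 at -1.04. Replication medians were -1.31 in #8520, -0.29 in NFSa, 0.05 in SCCVII and 0.02 in NR-S1. T and NK cell markers fell, 16 of 20 (median -0.82, adjusted p = 2.9e-12), with Cd3g at -1.18. Medians were -1.99 in NFSa (0.18 against untreated carbon-ion arm arrays), -0.73 in SCCVII, -0.13 in NR-S1 and 0.08 in #8520. MHC class II markers fell, 12 of 21 with 2 rises (adjusted p = 1.5e-09), with Ciita at -1.38. Unfolded protein genes fell, 16 of 27 (adjusted p = 3.5e-06), with Chac1 at -1.35, and 17 of 32 interferon-stimulated genes fell with 4 rises (adjusted p = 1.3e-06). Muscle markers fell, 15 of 27 with 2 rises (median -0.25, adjusted p = 1.9e-05, and 0.151 with tumours as the replicates). Medians were 3.30 in SCCVII and -2.46 in #8520. Adjusted over the list alone, 1 p53 target and 18 interferon genes fell, with the other counts the same. In all, 5750 of 13427 genes passed, 2842 higher and 2908 lower.

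At day 3 the interferon programme rose after gamma rays as it did after carbon ions. Mx1 rose by 2.43 (SE 0.0670, adjusted p = 3.7e-35), the interferon brake Usp18 by 2.29, Mx2 by 2.28 and Ifit1 by 2.23, with Apod at 2.33. Idi1 fell by 2.19 (SE 0.0668, adjusted p = 3.1e-33) and Sqle by 2.01, in 4 of 4 tumours, and Ino80b by 2.48 with a standard error of 0.410. Cdkn1a stood at 1.14, Mdm2 at 0.87, Ccng1 at 1.16 and Plk1 at -1.12. Of 32 interferon-stimulated genes 31 rose (median 1.12, adjusted p = 9.6e-29). All 33 mitosis genes (median -0.83, adjusted p = 1.7e-20) and all 32 replication genes (median -0.80, adjusted p = 3.2e-17) fell, with Bub1b at -1.21, and 20 of 31 DNA repair genes fell with 1 rise (adjusted p = 2.4e-05), with Rad51c at -0.95. Among 37 p53 targets 26 rose and 1 fell (median 0.41, adjusted p = 2.1e-13), with Ephx1 at 1.47. Hypoxia genes fell, 22 of 25 (median 0.16 in SCCVII, adjusted p = 2.2e-06), and MHC class II markers, 12 of 21 with 2 rises (adjusted p = 4.9e-06), with H2-Ab1 at -1.09. T and NK cell markers went both ways, 8 up and 5 down of 20 (median 0.08), with Ccl5 at 1.77. Their adjusted p was 0.0014, and 0.112 with the dimmest 50% of genes left out. Macrophage markers rose in 18 of 27 and fell in 6 (adjusted p = 0.0187, and 0.254 with an estimated correlation and 0.0698 without replicate 1 of NR-S1 at day 3). Muscle markers fell, 18 of 27 with 3 rises (median -0.35, adjusted p = 0.00040). Adjusted over the list alone, 22 DNA repair genes fell, with others the same. In all, 7261 of 13432 genes passed, 3108 higher and 4153 lower.

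At 50 Gy of gamma rays the 6 h response kept its parts, and interferon-stimulated genes fell. Cxcl2 rose by 3.52 (SE 0.0801, adjusted p = 3.4e-39), Retnlg by 3.20, S100a9 by 3.09, Celf5 by 3.06 and S100a8 by 2.92. Ung fell by 1.95 (SE 0.0536, adjusted p = 1.8e-35), the mitotic phosphatase Cdc25c by 1.75 and Sapcd2 by 1.66. Of 33 mitosis genes all fell (median -1.04, adjusted p = 2.8e-28), with Plk1 at -1.63, and 33 of 37 p53 targets rose with 2 falls (median 0.76, adjusted p = 1.1e-24), with Cdkn1a at 1.46, Mdm2 at 1.51 and Ccng1 at 1.59. Interferon-stimulated genes fell, 31 of 32 (median -0.63, adjusted p = 5.3e-18), with Iigp1 at -1.31 and medians from -1.59 in #8520 to 0.65 in NR-S1. Markers of T and NK cells fell, 15 of 20 (median -0.68, adjusted p = 3.3e-09), with Gzma at -1.90 and medians of 0.22 in NR-S1, -0.08 in SCCVII, -0.89 in #8520 and -2.25 in NFSa (-0.23 against the untreated arrays of the carbon-ion arm). Inflammatory genes rose, 18 of 26 with 2 falls (adjusted p = 7.4e-09), with Il6 at 2.32, and neutrophil markers 13 of 16 with 1 fall (adjusted p = 2.5e-12). Muscle markers rose, 26 of 27 (median 1.00, adjusted p = 9.0e-22), with Ckm at 1.65 and medians of 2.90 in SCCVII and -1.19 in NR-S1. Adjusted over the list alone, 19 inflammatory genes rose and 2 neutrophil markers fell, with others the same. In all, 6674 of 13432 genes passed, 3057 higher and 3617 lower. Directly against 30 Gy at 6 h, 3646 of 13452 genes differed, 1472 higher and 2174 lower at 50 Gy. Rgs1 was higher by 1.73 in 4 of 4 tumours (SE 0.0761, adjusted p = 5.6e-25), with Il6, Cd83, Ccl20 and Adipoq at 1.26, 1.28, 1.32 and 2.45. Gbp8 was lower, at -1.54 with -6.88 in NFSa, as were Gbp4, Ubd and Ighm, at -1.09, -1.12 and -1.18, and Lrrtm2. Of 32 interferon-stimulated genes 30 were lower at 50 Gy (median -0.51, adjusted p = 5.5e-25), but not in SCCVII (medians -0.29 and -0.54 at 30 Gy). Lower too were 31 of 33 mitosis genes (median -0.45, adjusted p = 1.1e-22), but not in NFSa (-0.60 and -0.63). Of 25 hypoxia genes 16 were higher (adjusted p = 1.3e-12), with Adm at 1.01, as were 21 of 26 muscle markers (adjusted p = 4.0e-17). Adjusted over the list alone, 32 mitosis genes were lower and 17 hypoxia genes higher.

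At day 1 and day 3 after 50 Gy, 4 of the 8 irradiated arrays at each time had the raised low end. At day 1 Celf5 rose by 2.24 (SE 0.0551, adjusted p = 5.0e-37), Ces2e by 1.93 and Ptprv by 1.92, in 4 of 4 tumours. Mal2 and Zfp750, epithelial genes dim outside NR-S1, were called higher. H2-Ab1, a chain of MHC class II, fell by 1.87 (SE 0.0476, adjusted p = 2.0e-36), Cyp51 by 1.81 and Anp32e by 1.75. Cdkn1a rose by 1.05 and Ccng1 by 1.45, and Mdm2 by 0.23 (adjusted p = 0.0417), with -0.92 in SCCVII and -0.65 in #8520, a call lost when any of 10 of the 16 arrays was left out (adjusted p up to 0.214). Of 37 p53 targets 29 rose and 2 fell (median 0.43, adjusted p = 8.7e-16), and 30 of 32 interferon-stimulated genes (median -0.63, adjusted p = 3.2e-09) and 19 of 20 T and NK cell markers (median -0.65, adjusted p = 7.1e-07) fell, the latter with 0.16 in NR-S1 and -1.98 in NFSa (0.13 against the untreated arrays of the carbon-ion arm). Of 31 keratinocyte markers 19 rose and 4 fell (adjusted p = 0.0044), and without the 8 arrays with the raised low end they were not called (adjusted p = 0.821), nor with quantile normalization, aligned low ends or the dimmest 50% of genes left out (adjusted p = 0.944, 0.475 and 0.521). At day 3 Fam3b, Ccl11, the eosinophil chemokine, Mx2, Oasl1 and the protease gene Pappa rose by 2.58, 2.56, 2.44, 2.42 and 2.42, and Cyp51 and Aspm fell by 2.43 and 2.31, with Ino80b at -2.73 (SE 0.389). Cdkn1a stood at 1.23, Ccng1 at 1.26 and Plk1 at -0.98, and Mdm2, at -0.05, did not pass (adjusted p = 0.677), but stood at 0.89 without the 8 arrays. Interferon-stimulated genes rose, 31 of 32 (median 1.19, adjusted p = 1.8e-22), macrophage markers 20 of 27 with 2 falls (adjusted p = 2.3e-05), and all 33 mitosis genes fell (median -1.08, adjusted p = 2.8e-13). Muscle markers rose at day 3, 18 of 27 with 4 falls (adjusted p = 0.0011, and 0.0590 with an estimated correlation, 0.118 with tumours as replicates and 0.408 against the untreated arrays of both arms), but without the 8 arrays the list fell (adjusted p = 1.8e-10). The counts adjusted over the list alone were the same except for 20 keratinocyte markers up and 5 down at day 1 and 19 muscle markers up at day 3. In all, 9157 genes passed at day 1, 3097 higher and 6060 lower, and 9865 at day 3, 3854 higher and 6011 lower. The share of higher calls, 33.8% and 39.1%, rose with quantile normalization and fell with aligned low ends. Over NR-S1 and NFSa alone, without the 8 arrays, 3989 and 6293 genes passed.

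Directly against 30 Gy, the genes with the largest differences at day 1 and day 3 lay in the tumours whose 50 Gy arrays had the raised low end. Dim genes were higher at 50 Gy, Mal2, Fmod, Akr1c18, Plch2 and Esrp1 at day 1, and Defb1, Zic1, Rbm20 and Catsperz at day 3, the last 2 by 1.49 and 1.33. In NFSa, which has no raised array, Defb1 was also higher. Bright genes were lower, Rpl26 and Rplp1, which code for ribosomal proteins, at -1.82 and -1.66 at day 1, and Rpl26, Rps9 and the chaperonin gene Tcp1 at -1.90, -1.62 and -1.66 at day 3. Esrp1 turned lower with quantile normalization or the low ends aligned, and without the 8 arrays Mal2 turned lower and Rpl26 and Cyp2j12 turned to 0.25 and 0.05. Rpl26 at day 1 was -3.84 in SCCVII and -3.97 in #8520 but 0.51 in NR-S1 and 0.00 in NFSa. Lhfp, Peli1 and Col6a3 at day 1 and Usp24 and Cyp2j12 at day 3 had the same pattern. Retnlg, higher by 1.43 at day 3, did not, at 2.12 in NR-S1, 3.89 in SCCVII, 0.49 in NFSa and -0.76 in #8520. Neutrophil markers were higher at both times, 11 of 16 with 3 lower (median 0.44, adjusted p = 1.1e-05) and 12 of 16 with 1 lower (adjusted p = 1.3e-05), the same adjusted over the list alone. Interferon-stimulated genes were lower at day 1, 21 of 32 with 1 higher (adjusted p = 0.0061, and 0.328 with an estimated correlation), and without the 8 arrays they were higher (adjusted p = 0.00063). Muscle markers were higher at day 3, 24 of 27 (adjusted p = 2.0e-17), and without the 8 arrays were not called (adjusted p = 0.380). In all, 8438 of 13442 genes differed at day 1, 2640 higher, and 7999 of 13449 at day 3, 3221 higher. The share of higher calls, 31.3% and 40.3%, rose with quantile normalization and fell with aligned low ends. Over NR-S1 and NFSa alone 617 and 1437 genes differed. With tumours as the replicates limma called 0 genes at 6 h, day 1 and day 3, and 1145, 1240 and 1167 had an unadjusted p under 0.05. Cdkn1a was not called between doses, with 0.10 at day 1 and 0.09 at day 3 (adjusted p = 0.372 and 0.438), and stood at -0.21 and -0.31 with quantile normalization. Mdm2 was lower at 50 Gy, at -0.69 and -0.92 (adjusted p = 7.3e-08 and 5.4e-11), but at 0.08 at day 1 without the 8 arrays. Ccng1 was not called, at 0.05 and 0.10, and Plk1 was at 0.12 and 0.14 (adjusted p = 0.0725 and 0.0314).

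The comparison between beams asks whether carbon ions do more than gamma rays at the same 30 Gy, with each beam set against its own untreated tumours. The responses were alike over genes, with a Pearson correlation across the 13384 genes of 0.704 at 6 h (genes are not independent replicates). Of 361 and 279 genes raised at least 1.5-fold by carbon ions and by gamma rays at 6 h 177 were shared, where unrelated lists of that size would share 7.53. The p53 list was called higher after carbon ions, 9 of 37 with 3 lower (adjusted p = 0.0382), and this was lost with quantile normalization, the dimmest 50% of genes left out, the untreated arrays of both arms or an estimated correlation (adjusted p = 0.355, 0.148, 0.143 and 0.228). Cdkn1a, Mdm2 and Ccng1 were not called, at 0.15, 0.39 and 0.05 (adjusted p = 0.498, 0.0571 and 0.761), and with quantile normalization Cdkn1a and Ccng1 turned to -0.27 and -0.14, while Plk1 was lower after carbon ions, at -0.25 (adjusted p = 0.0256). Cxcl1 rose more after carbon ions, by 1.42 (SE 0.0951, adjusted p = 3.6e-17) in 4 of 4 tumours, and Acod1, Ptx3 and Adipoq by 1.65, 1.45 and 1.80, with Ino80b at 2.07 (SE 0.534), which turned to -0.99 when the untreated arrays of both arms were the control. Ccl24 was lower in 4 of 4 tumours, at -1.49. Fgfbp1 was lower too, beside the muscle genes Xirp1, Mylk4 and Myod1 at -1.49, -1.39 and -1.25. Of 26 inflammatory genes 17 rose more after carbon ions (median 0.36, adjusted p = 8.7e-16), with Il6 at 1.02, and 10 of 16 neutrophil markers with 1 lower (adjusted p = 6.3e-15) and 13 of 32 interferon-stimulated genes with 2 lower (adjusted p = 4.3e-09), with Rsad2 at 0.82. T and NK cell markers were higher, 13 of 20 (median 0.53, adjusted p = 7.8e-14), muscle markers lower, 19 of 26 (median -0.59, adjusted p = 1.3e-19), immediate-early genes higher, 13 of 21 (adjusted p = 1.4e-11), and mitosis genes lower, 23 of 33 (median -0.27, adjusted p = 1.4e-11). These 4 calls ended when the untreated arrays of both arms were the control (adjusted p = 0.189, 0.549, 0.0546 and 0.0889). In NR-S1 the interferon, T and NK cell and muscle medians differed the other way, at -0.63, -0.05 and 0.77 after carbon ions and 0.77, 0.46 and -1.17 after gamma rays. Adjusted over the list alone, 18 inflammatory, 13 neutrophil, 15 interferon, 15 T and NK cell, 14 immediate-early and 11 p53 genes were higher, and 20 muscle markers, 26 mitosis and 5 p53 genes lower. In all, 2128 of 13384 genes differed, 1242 higher and 886 lower after carbon ions. The share of higher calls was 58.4%, and 47.4% with each array centred on its median. With tumours as the replicates limma called 0 genes, and 717 had an unadjusted p under 0.05.

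At day 1 the neutrophil response was the clearest difference between the beams. S100a8 was higher after carbon ions by 2.54 (SE 0.0730, adjusted p = 2.9e-33), with 3.97 in NFSa and 1.03 in NR-S1. Saa3, Cxcl2, Retnlg and S100a9 were higher by 2.58, 2.56, 2.45 and 2.44, in 4 of 4 tumours except Retnlg, which stood at -0.09 in SCCVII. Of 16 neutrophil markers 12 were higher and 1 lower (median 0.95, adjusted p = 1.3e-23), with Il1r2 at 2.25. The genes lower after carbon ions were Fam180a, Inmt, Ambp and the muscle troponin Tnnc1, between -1.19 and -1.08, and the keratin Krt17, which stood at -0.06 in NR-S1. Against the untreated arrays of both arms Tnnc1 turned to 0.41. Unfolded protein genes were higher, 18 of 27 with 1 lower (adjusted p = 5.1e-07), with Herpud1 at 0.99. T and NK cell markers were higher, 16 of 20 with 1 lower (adjusted p = 2.5e-09), but their medians were lower in NR-S1 (-0.40 and -0.13) and #8520 (-0.73 and 0.08), and with the untreated arrays of both arms as control were not called (adjusted p = 0.279), and the same held for the 13 inflammatory genes of 26 that were higher (adjusted p = 3.9e-06, then 0.287). Cdkn1a, Mdm2, Ccng1 and Plk1 were not called, at 0.18, 0.03, 0.11 and 0.19 (adjusted p = 0.340, 0.895, 0.426 and 0.0679), of which the first 3 turned to -0.29, -0.04 and -0.07 with quantile normalization. Muscle markers were higher, 23 of 27 with 3 lower (median 0.82, adjusted p = 3.2e-21), but lower in SCCVII (1.07 and 3.30). When adjusted over the list alone, 19 unfolded protein genes were higher and 2 lower, 16 p53 targets were higher, and the other counts were the same. In all, 3362 of 13379 genes differed, 2288 higher and 1074 lower, and 411 of the 449 that differed at least 1.5-fold were higher. Across genes the correlation of the responses was 0.532. With tumours as the replicates limma called 0 genes, and 867 had an unadjusted p under 0.05.

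At day 3 genes of lymphocytes, macrophages and antigen presentation were higher after carbon ions than after gamma rays over the mean of the 4 tumours, but of these only the macrophage median in each of them. Gbp8 was higher by 3.03 (SE 0.0835, adjusted p = 4.2e-34), with 10.02 in NFSa and -0.13 in #8520, and Calhm6, Acod1 and Apoc2 by 2.23, 2.16 and 2.16, with Ino80b at 2.62 (SE 0.550). The genes lower after carbon ions were Insl5, Cthrc1 and Stag3, from -1.35 to -0.97, and Lemd1 and Serpinb5. With both arms as control Lemd1 and Serpinb5 were not lower and Ino80b turned to -0.43. Of 20 T and NK cell markers 17 were higher (median 1.35, adjusted p = 4.4e-20), with Klrk1 at 1.85 and Cd3g at 1.83. Medians of this list after carbon ions and after gamma rays were 2.67 and 0.12 in NR-S1, 2.47 and -0.54 in NFSa (1.03 after gamma rays against the untreated arrays of the carbon-ion arm), 0.18 and 0.11 in SCCVII, and 0.74 and 1.19 in #8520. Macrophage markers were higher, 25 of 27 (median 0.74, adjusted p = 2.1e-17), with Clec7a at 2.09 and Ccr2 at 1.19, neutrophil markers 15 of 16 with 1 lower (median 0.88, adjusted p = 2.8e-18), and MHC class II markers 12 of 21 with 3 lower (median 0.58, adjusted p = 4.7e-13), with H2-Ab1 at 1.85 and Ciita at 1.78. Neutrophil medians were higher in NR-S1 and NFSa, but 0.16 and 0.16 in SCCVII and 0.43 and 0.45 in #8520, where MHC class II stood at -0.30 and -0.16. Interferon-stimulated genes were higher in 20 of 32 and lower in 1 (median 0.33, adjusted p = 7.7e-09), with Cxcl9 at 1.52, but lower in NR-S1 (1.18 and 1.98). Mitosis genes were lower, 30 of 33 (median -0.45, adjusted p = 7.9e-12), with Top2a at -0.60 (0.20 over the mean of all its probes), and replication genes, 24 of 32 (adjusted p = 1.7e-06). These 7 lists stayed called with both arms as control, which cancels between beams. Muscle markers were higher, 22 of 27 with 2 lower (median 0.68, adjusted p = 7.8e-15), but lower in SCCVII (-0.48 and 0.41). Cdkn1a and Mdm2 were not called, at -0.00 and -0.13 (adjusted p = 0.990 and 0.505), and Ccng1 and Plk1 were lower after carbon ions, at -0.31 and -0.33 (adjusted p = 0.0063 and 0.00081). Adjusted over the list alone, 18 T and NK cell markers were higher and 25 replication genes lower. In all, 4816 of 13382 genes differed, 2110 higher and 2706 lower, and 683 of the 796 that differed at least 1.5-fold were higher. Of 1156 and 536 genes raised at least 1.5-fold by carbon ions and by gamma rays 432 were shared, where unrelated lists would share 46.3, and the correlation across genes was 0.775. With tumours as the replicates limma called 0 genes, and 1520 had an unadjusted p under 0.05.

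**Figure D3:**
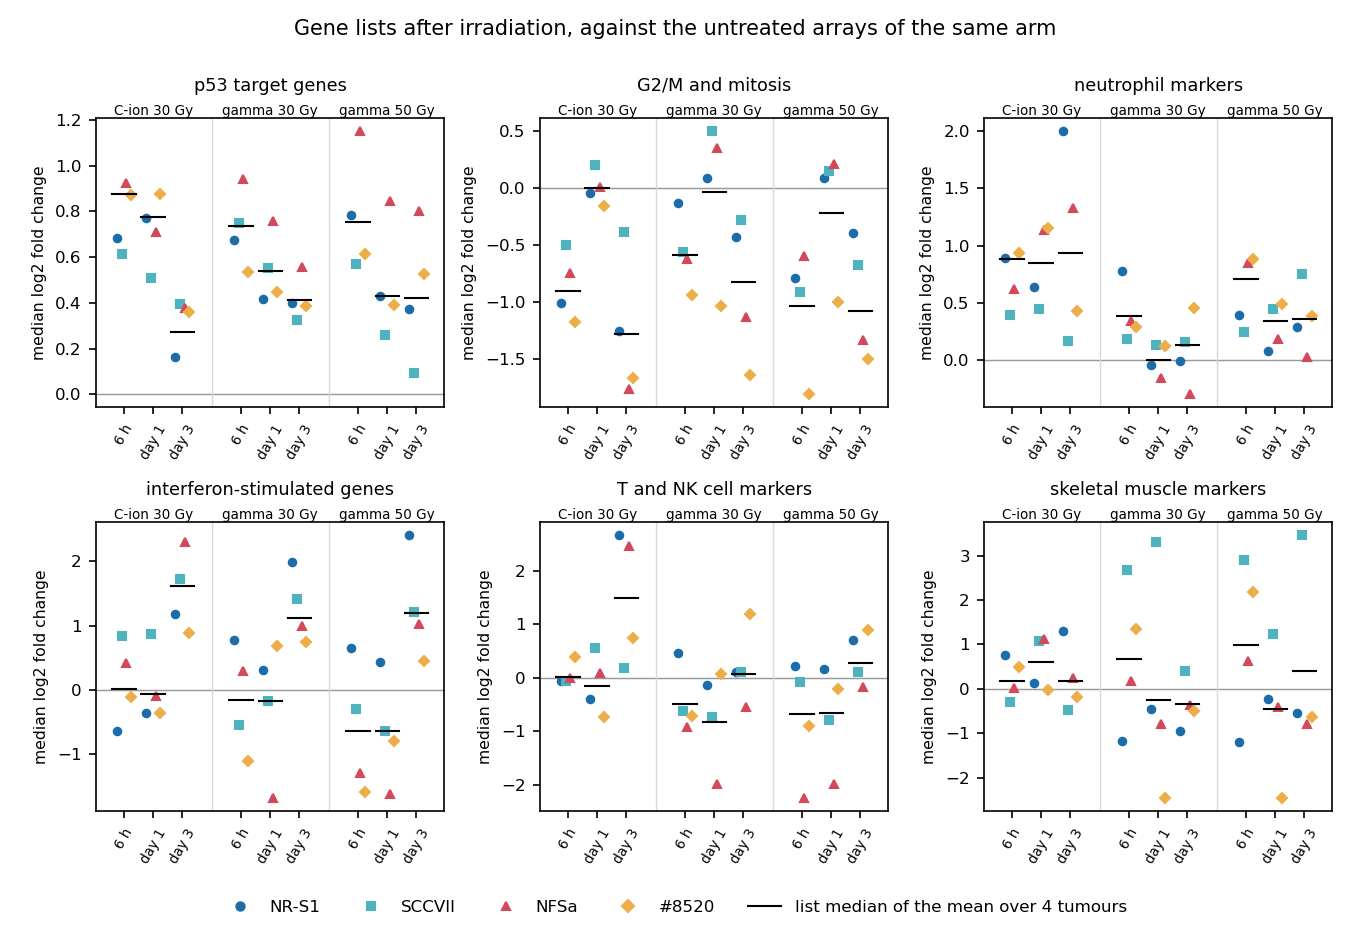
Median log2 change of 6 gene lists (vertical axis) by beam, dose and time (horizontal axis), with a point per tumour and a line at the list median of the mean over the 4 tumours. The p53 median lies above 0 in every tumour at every time, and the T and NK cell median at day 3 after carbon ions reaches 2.67 in NR-S1 and 2.47 in NFSa.

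Against the higher gamma dose of 50 Gy, lymphocyte, interferon and macrophage transcripts were higher after carbon ions over the mean of the 4 tumours, with some calls at day 1 and day 3 lost under other settings. At 6 h Gzma and Gzmb were higher by 1.79 and 1.61 in 3 of 4 tumours, and Gbp8 and Calhm6 by 2.29 and 1.67, with Ino80b at 2.15 (-0.91 against the untreated arrays of both arms). The muscle genes Mylk4, Tcap and Rbm20 were lower, at -2.03, -1.79 and -1.67, with Tekt1 and Cnksr1 at -1.60. Interferon-stimulated genes were higher, 28 of 32 (median 0.72, adjusted p = 1.9e-34), with Gbp3 at 1.32, T and NK cell markers 15 of 20 (adjusted p = 6.5e-16) and macrophage markers 17 of 27 (adjusted p = 9.9e-09), and muscle markers were lower, 26 of 27 (median -0.86, adjusted p = 6.6e-37). Of 6 red blood cell markers 3 were lower (adjusted p = 0.0340, and 0.0950 with an estimated correlation, 0.0666 with the offset, 0.112 with no filter and 0.681 against the untreated arrays of both arms). At day 1 Acod1, Cxcl2, Calhm6 and Hdc were higher by 2.57, 2.43, 2.31 and 2.24, neutrophil markers were higher in 11 of 16 and lower in 2 (adjusted p = 3.1e-07), and interferon-stimulated genes in 29 of 32 with 2 lower (adjusted p = 4.2e-09). At day 1 the call of T and NK cell markers (16 of 20 higher, adjusted p = 7.8e-06) was lost against the untreated arrays of both arms (adjusted p = 0.224), and that of macrophage markers (15 of 27 higher and 2 lower, adjusted p = 0.0118) with an estimated correlation (adjusted p = 0.240). Lemd1, Krt17, Esrp1, Dsp and Epn3, epithelial genes dim outside NR-S1, were lower, but between -0.36 and 0.12 in NR-S1, and of 31 keratinocyte markers 16 were lower and 6 higher (adjusted p = 0.0021), but without the 8 raised arrays these were not called (adjusted p = 0.639), nor with aligned low ends or the dimmest 50% left out (adjusted p = 0.766 and 0.920). Esrp1 was not lower with quantile normalization. At day 3 Gbp8, Calhm6 and Acod1 were higher by 2.52, 2.28 and 2.11, with Ino80b at 2.87 (-0.19 against the untreated arrays of both arms) and Dsp and Rbm20 lower, at -1.79 and -1.77, as were Lemd1, Krt17 and Esrp1. Klrk1 was higher by 1.81 in 4 of 4 tumours (SE 0.123, adjusted p = 1.1e-17). T and NK cell markers were higher in 18 of 20 (median 1.13, adjusted p = 4.7e-14), though in #8520 the median was 0.74 after carbon ions and 0.89 after 50 Gy, and that of NFSa after 50 Gy was -0.17 with its own untreated arrays and 1.44 with those of the carbon-ion arm, macrophage markers in 23 of 27 with 2 lower (adjusted p = 2.7e-06), MHC class II markers in 12 of 21 with 2 lower (adjusted p = 5.9e-07), with Cd74 at 1.20, and B cell markers in 8 of 13 with 1 lower (adjusted p = 0.0020), with Jchain at 1.80. Interferon-stimulated genes were higher at day 3 in 20 of 32 and lower in 3 (adjusted p = 0.0029, and 0.235 with an estimated correlation and 0.0606 with aligned low ends). In NR-S1 the interferon median was lower after carbon ions than after 50 Gy at each time (-0.63 and 0.65, -0.36 and 0.44, 1.18 and 2.41), as was that of T and NK cells at 6 h and day 1 (-0.05 and 0.22, -0.40 and 0.16), with muscle higher at 6 h (0.77 and -1.19). In #8520 T and NK cells at day 1 (-0.73 and -0.21), macrophages at day 1 and day 3 (0.10 and 0.13, 0.67 and 0.76) and MHC class II at day 3 (-0.30 and -0.23) were lower, and in SCCVII macrophages at 6 h (-0.02 and 0.12), with neutrophils alike at day 1 (0.44 and 0.44). Cdkn1a was not called at any time, at -0.20, 0.09 and -0.09 (adjusted p = 0.321, 0.617 and 0.599). Mdm2 was alike at 6 h, at -0.01, and higher after carbon ions at day 1 and day 3, by 0.73 and 0.79 (adjusted p = 3.5e-05 and 1.0e-05), but lower without the 8 arrays, at -0.35 and -0.53. Ccng1 differed at day 3 alone, at -0.41, and Plk1 by 0.32 at 6 h and -0.47 at day 3 (adjusted p = 0.0020 and 2.7e-06). Of 27 muscle markers 24 were higher at day 1, 2 lower (median 1.00, adjusted p = 1.7e-13), but not in SCCVII (1.07 and 1.25). Adjusted over the list alone, 3 muscle and 17 keratinocyte markers were lower at day 1. Higher were 29 interferon and 18 macrophage genes at 6 h and 14 MHC class II at day 3. In all, 3072, 7142 and 6630 genes differed (2812 at day 1 over NR-S1 and NFSa alone), 1829, 5488 and 3729 higher. The share higher at day 1 and day 3 depended on the processing. With tumours as replicates limma called 0 genes each time, and 610, 951 and 1136 had an unadjusted p under 0.05.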

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

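The tests of a varying share of muscle and of a muscle response shared by both beams were chosen after the muscle values had been seen, and the test of whether the arrays of a group share RNA was chosen before.

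Carbon-ion responses differed between the tumours by a moderated F test for 6035 of 13415 genes at 6 h, 7824 of 13417 at day 1 and 8298 of 13415 at day 3. Of these genes 173, 414 and 437 moved at least 1.5-fold up in at least 1 tumour and 1.5-fold down in another. At 6 h the largest F values were those of Gbp4 (403.6), Gbp8 (343.6), Tnni1 (316.8), Cxcl9 (300.2) and Retnlg (246.2). At day 1 they belonged to Gbp8 (671.1), Tnni1 (475.4), Gbp4 (471.8), Retnlg (436.2) and Cyp2f2 (385.8). At day 3 Psca (770.7), Sprr2g (697.4), Crct1 (663.4) and Sprr2f (632.8) stood above Gbp8 (572.8). The error behind each F is the spread between the 2 arrays of a group, and the labels do not say whether these came from separate animals.

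Probes with no gene name, which enter no other comparison, also changed after carbon ions. At 6 h 2318 of 10330 such probes passed, 1053 higher and 1265 lower, with the largest change at 2.83. At day 1 3051 of 10338 passed, 1182 higher and 1869 lower, up to 2.63, and at day 3 4824 of 10334, 1627 higher and 3197 lower, up to 3.99.

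Tnni1 is a skeletal muscle gene, and the muscle list moved up in some groups and down in others, at 6 h after 30 Gy of gamma rays by 2.67 in SCCVII and by -1.17 in NR-S1. A response to radiation shared by both beams stays open: carbon ions and 30 Gy of gamma rays moved the list median the same way in 5 of 12 combinations of tumour and time, but the untreated arrays of the arms differ in this list and serve all 3 times. A varying share of leg muscle in the tissue taken stays open as a candidate source: the 27 members went together across groups at a mean correlation of 0.761, against at most 0.194 in 100 random lists, with abundant Tnni2, Acta1 and Eno3 at mean log2 levels of 6.66, 6.61 and 5.93. The arrays of a group may also carry the same RNA or pool, since the list mean varied between them 1.20 times as much as that of random lists (SD 0.0593, with a 95th percentile of 0.0649 for random lists), while its SD between groups was 1.02 against 0.123. A muscle response that differs between beams or tumours was not tested.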

How the results depend on the processing

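Leaving out the 8 arrays with a raised low end and aligning the low ends were chosen after the data were seen. Depth here is signal over background: the 1st percentile of intensity ran from 0.0128 to 0.378 between arrays against medians of 1.02 to 1.07, and the background step behind it is not known. An intensity trend with a robust prior moved no count by over 1.5 times of the 27 compared, and left the 369 values of named genes on their side of the threshold. No count moved that far either under quantile normalization, median centring, the offset, the mean of all probes or aligned low ends. Among the named values 368 of 369 kept direction and side of the threshold with centring, 367 of 369 with the offset, 366 of 369 with the mean of probes, 344 of 369 under quantile normalization and 354 of 367 with aligned low ends. Of 242 list calls, 76 were lost with an estimated correlation, 21 under quantile normalization, 18 with no filter, 14 with aligned low ends, 9 with the mean of probes and 2 with fry, which added 110. Untreated arrays of both arms as control lost 49 of 188, tumours as replicates 28 of 242, the dimmest 50% of genes left out 30 of 241, and without the 8 arrays 9 of 59 were lost and 2 reversed.

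Asking for a fold of at least 1.5 as well, which can only remove genes, left 535, 589 and 2083 after carbon ions at the 3 times, 430, 526 and 1088 after 30 Gy of gamma rays and 1068, 1602 and 2559 after 50 Gy, where 5433, 5649 and 9154, 5060, 5750 and 7261 and 6674, 9157 and 9865 had passed. It left 230, 449 and 796 of 2128, 3362 and 4816 between carbon ions and 30 Gy of gamma rays, 408, 1327 and 1256 of 3072, 7142 and 6630 between carbon ions and 50 Gy, and 245, 955 and 955 of 3646, 8438 and 7999 between the doses. From 6 h to day 3 it left 1412 of 8393, between carcinomas and fibrosarcomas 3121 of 9881, in every tumour 117, 78 and 545 of 416, 311 and 1706, and 34 of 114 list calls.

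With tumours as the replicates, 4 against 4 in place of 8 against 8 arrays, limma called 389, 24 and 1705 genes after carbon ions, 11, 8 and 61 after 30 Gy of gamma rays and 4, 3 and 5 after 50 Gy, with 2225, 1668 and 4240, 1944, 1632 and 2854 and 1773, 2076 and 3388 at an unadjusted p under 0.05. It called 0 in the 6 differences between beams, the 3 between doses and that between carcinomas and fibrosarcomas, with 717, 867 and 1520, 610, 951 and 1136, 1145, 1240 and 1167 and 781 at an unadjusted p under 0.05. From 6 h to day 3 it called 431 (3178 at an unadjusted p under 0.05), and 112 list calls stood against 114. Of 354 named values 103 kept their direction and their side of the threshold, called or not, 251 kept only their direction and 0 reversed.

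With the untreated arrays of both arms as control, the counts for carbon ions less 30 Gy of gamma rays went from 2128 to 7431, from 3362 to 8664 and from 4816 to 8755 at the 3 times, that against 50 Gy at 6 h from 3072 to 8052, and genes changed in every tumour at day 1 from 311 to 599. The control then cancels between beams, and arm differences remain in these values. Reversed were, with the first values in parentheses, for carbon ions less 30 Gy Cdkn1a at -0.24 (0.15) and Ino80b at -0.99 (2.07) at 6 h, Cdkn1a at -0.21 (0.18) and Tnnc1 at 0.41 (-1.09) at day 1, and Ino80b at -0.43 (2.62), Lemd1 at 0.00246, Mdm2 at 0.25 (-0.13) and Serpinb5 at 0.24 at day 3. Against 50 Gy they were Ino80b at -0.91 (2.15) and Mdm2 at 0.38 (-0.006) at 6 h, Cdkn1a at -0.31 (0.0852) and Ino80b at -0.48 (2.58) at day 1 and Ino80b at -0.19 (2.87) at day 3, and the cause was not tested.

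Without the 8 raised arrays, which leaves NR-S1 and NFSa in these comparisons, counts went from 9157 to 3989 at day 1 and from 9865 to 6293 at day 3 after 50 Gy, from 7142 to 2812 between carbon ions and 50 Gy at day 1, and from 8438 to 617 and from 7999 to 1437 between the doses at day 1 and day 3. Mdm2 then stood at 0.89 (-0.0484) at day 3 after 50 Gy, and at -0.35 (0.73) and -0.53 (0.79) for carbon ions less 50 Gy at day 1 and day 3, with Cdkn1a at 0.0753 (-0.0917) at day 3. Between the doses the reversed values were Mal2 at -0.14, Mdm2 at 0.084 (-0.69), Plk1 at -0.12 (0.12) and Rpl26 at 0.25 (-1.82) at day 1, and Cdkn1a at -0.11 (0.0886), Cyp2j12 at 0.0493 (-1.66) and Plk1 at -0.0345 (0.14) at day 3. Whether the arrays or the tumours left out cause this was not tested.

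Quantile normalization reversed Mdm2 at 0.13 (-0.0484) at day 3 after 50 Gy. For carbon ions less 30 Gy of gamma rays it reversed Ccng1 at -0.14 (0.0524) and Cdkn1a at -0.27 (0.15) at 6 h, and Ccng1 at -0.0651 (0.11), Cdkn1a at -0.29 (0.18) and Mdm2 at -0.0356 (0.0335) at day 1. It also reversed Cdkn1a at -0.0829 (0.0852) and Esrp1 at 0.0914 for carbon ions less 50 Gy at day 1, Cdkn1a at -0.21 (0.0994) and Esrp1 at -0.23 between the doses at day 1, and Cdkn1a at -0.31 (0.0886) at day 3. Aligned low ends gave Mdm2 at 0.00554 (-0.006) at 6 h and Esrp1 at 0.30 at day 1 for carbon ions less 50 Gy, Esrp1 at -0.44 and Plk1 at -0.0105 (0.12) between the doses at day 1 and Plk1 at -0.0345 (0.14) at day 3. The offset gave Mdm2 at 0.000974 (-0.006) for carbon ions less 50 Gy at 6 h, and the mean of probes Top2a at 0.20 (-0.60) for carbon ions less 30 Gy at day 3. For these values the cause was not tested.

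The share of called genes that were higher was, in percent with quantile normalization and aligned low ends in parentheses, 33.8 (49.4 and 13.4) at day 1 and 39.1 (49.7 and 23.2) at day 3 after 50 Gy, 76.8 (52.9 and 97.2) and 56.2 (44.9 and 82.7) for carbon ions less 50 Gy, and 31.3 (51.7 and 7.89) and 40.3 (56.7 and 15.3) between the doses. For carbon ions less 30 Gy at 6 h it was 58.4, and 47.4 with centring. Quantile normalization moved the median of all genes by -0.14 for carbon ions less 50 Gy at day 1 and by 0.10 between the doses at day 1. Aligned low ends moved it by -0.14 and -0.14 after 50 Gy at day 1 and day 3, by 0.14 and 0.14 for carbon ions less 50 Gy, and by -0.13 and -0.12 between the doses.

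With no filter, which tests more genes, counts went from 7142 to 10837 and from 6630 to 10209 for carbon ions less 50 Gy at day 1 and day 3 and from 7999 to 12085 between the doses at day 3. With the dimmest 50% left out, which tests fewer, they went from 3362 to 2190 for carbon ions less 30 Gy at day 1 and from 3072 to 2032 for carbon ions less 50 Gy at 6 h. With only the arrays compared, which leaves fewer degrees of freedom, genes changed in every tumour went from 416 to 240 at 6 h and from 311 to 178 at day 1. The replicate block used 72 arrays with numbers 1 and 2, left out 16 and called 5543 genes at 6 h after carbon ions. It moved no count by over 1.5 times in the 21 compared, which hold no gamma group of day 1, and gave 98 list calls of 147, against 95 without it. Arrays of the same number deviated together at a correlation over 0.1 in 17 of 64 pairs, 8 of them among the 10 of NFSa in the gamma arm. Since no set of tumour and arm had every pair over that value, the numbers were not taken as pairs.

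Each array left out in turn, with the lone array left in a group taken to vary like the others, moved no count by over 1.5 times. Ranges were 4993 to 5259, 5201 to 6038 and 8819 to 8877 after carbon ions, 4668 to 4939, 5344 to 5530 and 6884 to 7061 after 30 Gy and 6327 to 6486, 8771 to 8960 and 9558 to 9751 after 50 Gy. They were 1826 to 2195, 2971 to 3804 and 4413 to 4927 for carbon ions less 30 Gy, 2729 to 3089, 6722 to 7192 and 6298 to 6686 less 50 Gy, and 3178 to 3591, 8051 to 8207 and 7549 to 7948 between the doses. Values turned in sign within the ranges of -0.00526 to 0.11 and -0.0787 to 0.0667 for Ccng1 and Mdm2 for carbon ions less 30 and 50 Gy at 6 h, -0.12 to 0.18 for Mdm2 and -0.0599 to 0.0537 for Cdkn1a for carbon ions less 30 Gy at day 1 and day 3, and -0.00362 to 0.10 for Ccng1 between the doses at day 1, none of them called. Calls ended by the loss of an array were Mdm2 at day 1 after 50 Gy (10 of 16 arrays, to adjusted p = 0.214 and 0.14 without #8520 gamma 50 Gy day 1 replicate 4), Plk1 for carbon ions less 30 Gy at 6 h (4 of 32 arrays, to adjusted p = 0.0759 and -0.20 without #8520 C-ion arm untreated replicate 1), Krt17 at day 1 (6 of 32 arrays, to adjusted p = 0.132 and -0.70 without NFSa C-ion 30 Gy day 1 replicate 2), Plk1 between the doses at day 3 (8 of 16 arrays, to adjusted p = 0.191 and 0.0865 without NFSa gamma 50 Gy day 3 replicate 2) and Plk1 from 6 h to day 3 (4 of 16 arrays, to adjusted p = 0.116 and -0.10 without NR-S1 C-ion 30 Gy day 3 replicate 2).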

Other observations

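The tests of the T and NK cell list, and that of a larger effect of the gamma dose at day 3 alone, were chosen after the values had been seen, and the other tests of the gamma dose and those of other splits of the arrays were chosen before.

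The untreated arrays of the arms differed from each other, by 6616 genes in NR-S1, 6239 in SCCVII, 6624 in NFSa and 4783 in #8520. Over the mean of the 4 tumours the carbon-ion arm was higher in 23 of 27 muscle markers and lower in 3 (median 0.58, adjusted p = 6.8e-09), and lower in 11 of 20 T and NK cell markers and higher in 1 (median -0.39, adjusted p = 0.00131), by limma's camera. The T and NK difference came from NFSa: the list median of the gamma arm less the carbon-ion arm was 2.16 in NFSa, 0.09 in #8520, -0.25 in SCCVII and -0.56 in NR-S1. Mitosis genes were higher in 21 of 33 and lower in 5 (adjusted p = 0.0332, and 0.357 with an estimated correlation), and MHC class II markers lower in 13 of 21 and higher in 3 (adjusted p = 0.00922, and 0.127 with an estimated correlation). What set the arms apart, by date, animals or handling, is not given in the labels. The arrays of NR-S1 at day 1 after carbon ions differed most within a group, with an SD of 0.326, and were the only ones of 44 groups that did not match each other best.

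The T and NK cell list fell at 6 h and day 1 after 30 Gy of gamma rays, with medians of -0.49 and -0.82, and of -0.09 and -0.23 against the untreated arrays of the carbon-ion arm. A loss of these cells after either beam is argued against at 6 h, where the median after carbon ions was 0.0256 (quartiles -0.121 and 0.123). At day 1 it stays open: after carbon ions the median was -0.149, with -0.40 in NR-S1, 0.56 in SCCVII, 0.10 in NFSa and -0.73 in #8520, and the list was not called lower by limma's camera (adjusted p = 0.0701) but was with tumours as the replicates, the untreated arrays of both arms or fry (adjusted p = 0.0465, 0.000247 and 2.3e-05). A higher level in the untreated gamma-arm arrays stays open for NFSa, where the medians at 6 h and day 1 against those of the carbon-ion arm were 1.21 and 0.18 and not -0.92 and -1.99, and is argued against at 6 h in SCCVII and #8520, at -0.73 and -0.90 against -0.63 and -0.71 with their own. An effect of gamma rays alone was not tested.

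More genes differed between 50 and 30 Gy of gamma rays at day 1 and day 3 than at 6 h, 8438 and 7999 against 3646. A larger effect of dose at both later times is argued against in the tumours without raised arrays, NR-S1 and NFSa, where the day 1 count was 0.331 times the count of 1832 at 6 h, with 806 against 1089 genes in NR-S1 and 364 against 2127 in NFSa. A larger effect at day 3 alone stays open: their joint count of 1388 was 0.758 times that at 6 h, but the 2 tumours differ, at 1.59 times in NR-S1 and 0.154 times in NFSa. The raised low end of 8 arrays stays open as a cause. Tumours with them had 10.6 times the called genes of the others at day 1 and day 3, and 1.86 times at 6 h. Their dimmest 25% of genes stood higher at 50 Gy by medians of 0.28 to 0.30. The pattern stayed with quantile normalization (8127 and 8112 genes) and aligned low ends (9316 and 8516). A larger dose effect confined to SCCVII and #8520 was not tested.

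Other splits of the arrays within tumours were fitted likewise, at most 100 per comparison, the real one included. They take the 2 arrays of a group as separate samples, which the labels do not state. They speak for these arrays, not further tumours. Limma with tumours as replicates called 3 to 1705 genes against untreated tumours and 0 between the doses. In that sense chance can be excluded against untreated tumours, but not differences like those between untreated arms. After carbon ions the real counts at the 3 times were 5433, 5649 and 9154, the highest others 4424, 4507 and 8381. After 30 Gy of gamma rays they were 5060, 5750 and 7261 against 4017, 5244 and 5720. After 50 Gy they were 6674, 9157 and 9865 against 5807, 8902 and 8422. The same holds from 6 h to day 3 (8393 against 7889) and between the doses at 6 h (3646 against 3377). Between the doses at day 1 and day 3 splits cannot exclude chance, as tumours with raised arrays had most calls. Counts were 8438 and 7999 against 8797 and 8065, with 5 and 2 of 100 splits as high. Between the beams the 8 splits are too few. The counts against 30 Gy were 2128, 3362 and 4816 with highest others of 3040, 4959 and 4236, and against 50 Gy 3072, 7142 and 6630 with highest others of 3541, 7786 and 7596. The 3 splits of the untreated tumours are too few as well, at 9881 with a highest other of 9014.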
